A study of Mus musculus with 4 samples.

How the data were processed

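Single-cell RNA sequencing was done on bone marrow of C57BL6/J mice, a common inbred laboratory strain. The labels give 2 control samples and 2 stroke samples. Per the labels' protocols, marrow cells were stained with antibodies against CD3, CD4, CD8a, CD19 and Ter119 and against the neutrophil protein Ly6G, and the fraction negative for all of them was sorted. Propidium iodide was added to mark dead cells. Libraries were made with the 10x Genomics Chromium 3′ v3.1 chemistry, which counts transcripts from their 3′ ends with unique molecular identifiers (UMIs), and the stated sequencing target was 20000 reads per cell.

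The deposited values were raw UMI counts per gene and cell, made by the authors with Cell Ranger 7.1.0 per the file headers and the submitters' processing notes, on genome build mm10 per the same notes. Barcodes and gene names were deposited with the counts. The gene annotation, whether intronic reads were counted, and whether depth was equalised between libraries were not given in the sources used here. The matrix held 32285 genes and 32121 cell barcodes with 247861870 UMIs. Barcodes ended in 1 of 4 suffixes, taken here as 4 libraries and called libraries 1 to 4 after the suffix.

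No text in the files used here tied a suffix to a labelled sample. Condition was never read from suffix order, barcode order or expression. A comparison of stroke with control, although planned, was therefore not run, and the design fixed for this case was used: cell classes were compared over all cells. The libraries were not treated as replicates of a group. They are given as values, ranges and medians, with no mean ± SD and no p-value. Intervals are 95% exact intervals (Clopper-Pearson for shares, the conditional binomial interval for ratios of counts) and cover counting error only.

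Barcodes were kept with at least 500 detected genes and under 10% mitochondrial UMIs, which removed 1426. Doublets were called with Scrublet within each library at an expected rate of 6%. It marked 1726 of the remaining barcodes (5.62%), which were left out. The 28969 kept cells held 222290156 UMIs, with a median of 5763 per cell. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen (scanpy 1.11.5). The 420 measured genes of the fixed gene lists were kept out of the variable genes, so that their levels could be compared between clusters. Values were scaled and limited to 10, and reduced to 30 principal components. The 15 nearest neighbours of each cell gave a shared-neighbour graph, which was clustered with the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). This gave 33 clusters.

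Clusters were named "X-like" from marker lists of 19 cell classes. A marker counted for a cluster if at least 10% of its cells had a UMI and its level was at least 2 times that of all other cells, after adding 10 CPM (the standard scaling of counts to a fixed total) to both. The class with the most such markers gave the name. Ties were settled by the mean scaled marker level. A cluster stayed unnamed with fewer than 3 such markers, or when another class had more markers among its 10 leading genes seen in at least 25% of cells. It also stayed unnamed if its median UMI count, relative to the library median, was under 0.333 and no marker of the class was among these genes. By these rules 57 cells (0.197%) stayed unnamed. The names are rebuilt from RNA markers and may differ from those of the authors.

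For each pair of classes, counts were summed over cells and expressed as CPM of the class total. A gene of a list was counted as higher if the ratio was at least 2, its interval excluded 1 and the ratio lay above 1 in every library. It was counted as lower if the ratio was at most 0.5 under the mirrored conditions. Markers of either class were not counted. The 20 gene lists named 430 distinct genes, of which 10 were not matched to a single row. For each list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. In these medians, 3 counts were added to each class sum, scaled to its total. The genes named in the text are, per list, up to 3 counted as higher and up to 3 counted as lower with the largest ratios and at least 50 CPM in the higher class. Per class, the 3 markers with the highest CPM are given. A comparison needed 50 cells in each class. That of mature neutrophils with their precursors was not made, because no cluster was named mature neutrophil-like.

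To compare cycling across depths, each cell was thinned to 2000 UMIs, and the share of cells with at least 3 UMIs from the G2/M list was taken. Shallower cells were left out.

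The alternatives were Leiden resolutions of 0.5 and 2, 4000 variable genes, list genes left among the variable genes, called doublets kept in, a minimum of 1000 genes per cell, scaling by TMM factors (edgeR 4.0.16 in R 4.3.3), the median of the library ratios, only genes with at least 10 CPM in either class, and leaving out each library in turn. Gene lists, markers, the call rule and these alternatives were fixed before the data were examined.

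The steps were tested on simulated data. Counts were drawn from the real mean profiles and class totals with 200 genes changed. All libraries of a class shared the same profile, so real differences between libraries were not simulated. Of genes changed 2.5-fold, 100% were called in the classical monocyte against progenitor comparison (12015 genes), 97.9% in the progenitor against HSPC (haematopoietic stem and progenitor cell) comparison (12507 genes), 89.0% in the nonclassical against classical comparison (11698 genes) and 100% in the dendritic cell comparison (11772 genes). All genes changed 4-fold were called in each of the 4. Of genes changed 1.5-fold, 1 of 57 was called in the nonclassical comparison and 0 in the others. Unchanged genes were called 0, 16, 53 and 29 times in the same order, of which 7 in the nonclassical comparison had 10 CPM or more and none did in the others. Clustering of 1800 cells simulated from 6 class profiles (32285 genes) placed 99.9% in a cluster led by their own profile. These profiles came from classes made by the same clustering, and the simulated cells of a class differed by counting error and depth only. The value therefore checks that the steps run and cannot tell how well the real clusters are separated. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Gene positions were taken from a GENCODE mouse annotation of the mm10 build, matched on the deposited gene identifiers for all 181 named genes and markers.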

Results

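The data were counts of transcripts in single bone marrow cells of mice from a study of how marrow myelopoiesis stands long after stroke, with 2 control and 2 stroke samples. The cells came from a sort against lymphoid markers, the erythroid marker Ter119 and the neutrophil marker Ly6G. All cells were in 1 matrix with 4 barcode suffixes. The suffixes are not tied to a labelled sample here, so no stroke effect is reported and values are given for libraries 1 to 4 without their conditions. The 4 libraries held 7168, 8002, 7662 and 9289 barcodes and 56384522, 58162182, 62427786 and 70887380 UMIs. Median UMIs per barcode were 6048.5, 5433.5, 6044 and 5606. After filters, 6451, 7235, 6959 and 8324 cells were kept. Intervals in brackets are 95% and cover counting error only.

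The first question was which progenitor and mature cells the sorted marrow held. Classical monocyte-like cells were the most frequent class, at 9281 of 28969 cells or 32.0% (31.5 to 32.6), with 29.0% to 33.9% in the libraries and a median of 33.0%. They carried F13a1, the A subunit of coagulation factor XIII, at 2528 CPM against 339 in all other cells, together with Ly6c2 at 2117 and fibronectin (Fn1) at 1506 CPM. Neutrophil precursor-like cells made up 10.4% (10.0 to 10.7), with 9.34% to 12.3% in the libraries. In these cells the secondary granule genes Camp, Ngp and Lcn2 reached 43456, 42625 and 14199 CPM. Their 10 most abundant transcripts took 36.0% of their counts. No cluster was named mature neutrophil-like, in a sort against Ly6G-positive cells. A precursor cluster of 1241 cells did pass 6 mature neutrophil markers beside 10 precursor markers, so later stages may lie within this class. Ly6g was measured at 108 CPM in the neutrophil precursor-like cells and at 0.431 CPM in classical monocyte-like cells.

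The 2 progenitor classes together made up 12.0% of cells (11.6 to 12.3), with 11.2% to 12.7% in the libraries. Granulocyte-monocyte progenitor-like cells (GMP-like) were 2416 cells or 8.34% (8.02 to 8.66), a share that fell to 5.19% at Leiden resolution 0.5. They carried the primary granule proteases Elane and Prtn3 at 7266 and 6239 CPM and myeloperoxidase (Mpo) at 4738 CPM. Cells like haematopoietic stem and progenitor cells (HSPC-like) were 1050 or 3.62% (3.41 to 3.85). They carried the stem cell niche ligand Angpt1 at 1120 CPM, Adgrl4 at 738 CPM and the homeobox gene Meis1 at 409 CPM. Median depth was 18002 UMIs per GMP-like cell, 8188.5 per HSPC-like cell and 6258 per classical monocyte-like cell.

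Plasmacytoid dendritic cell-like cells made up 8.94% (8.61 to 9.28), with Tcf4, the transcription factor that specifies this lineage, at 3698 CPM, Runx2 at 2697 CPM and Ly6d at 2335 CPM. Conventional dendritic cell-like cells made up 3.70% (3.48 to 3.92), with the lectins Cd209a at 418 CPM and Clec10a at 224 CPM and the receptor Flt3 at 129 CPM. Nonclassical monocyte-like cells made up 1.56% (1.42 to 1.71), with 1.05% to 2.09% in the libraries. Their leading markers were Adgre4 at 1021 CPM, Pou2f2 at 816 CPM and the fractalkine receptor Cx3cr1 at 658 CPM. Basophil or mast cell-like cells made up 3.03% (2.84 to 3.24), with the proteases Prss34, Mcpt8 and Cpa3 at 16789, 14594 and 2778 CPM. Erythroid-like cells made up 2.74% (2.56 to 2.94), with the haemoglobin genes Hbb-bs, Hba-a1 and Hbb-bt at 9771, 4279 and 3202 CPM. These values average over clusters that differ. The larger one, 76.9% of the class, had Car1, Car2 and Gata1 but no haemoglobin gene among its leading genes. It passed 9 erythroid and 7 HSPC markers. Haemoglobin genes led the smaller one of 184 cells, of which 106 were in library 3. Hbb-bs ranged from 3863 to 11490 CPM in the libraries.

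Lymphoid classes made up 25.4% of kept cells (24.9 to 26.0), in a fraction sorted against CD3, CD4, CD8a and CD19. T cell-like cells were 10.2% (9.81 to 10.5), with Trbc2 at 1043 CPM and the CD3 chains Cd3d and Cd3g at 809 and 639 CPM. B lineage-like cells were 9.62% (9.29 to 9.97), with the early B cell factor Ebf1 at 6906 CPM, Vpreb3 at 2745 CPM and Cd79a at 2585 CPM. The B lineage-like share was 8.17%, 13.6%, 3.88% and 12.1% in libraries 1 to 4, a wider relative spread than that of the T cell-like share at 9.15%, 9.08%, 12.4% and 10.0%. NK cell-like cells were 4.52% (4.28 to 4.76), with Ccl5 at 5534 CPM, granzyme A (Gzma) at 2255 CPM and Ncr1 at 1241 CPM. Cells like innate lymphoid cells of type 2 were 0.753% (0.656 to 0.859), with Il7r at 1173 CPM, Rora at 1031 CPM and Gata3 at 729 CPM. Plasma cell-like cells were 0.390% (0.322 to 0.469), with Igha at 31596 CPM, Jchain at 27275 CPM and Mzb1 at 1993 CPM. The sort sets these shares, so they do not give the composition of whole marrow.

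**Figure D1:**
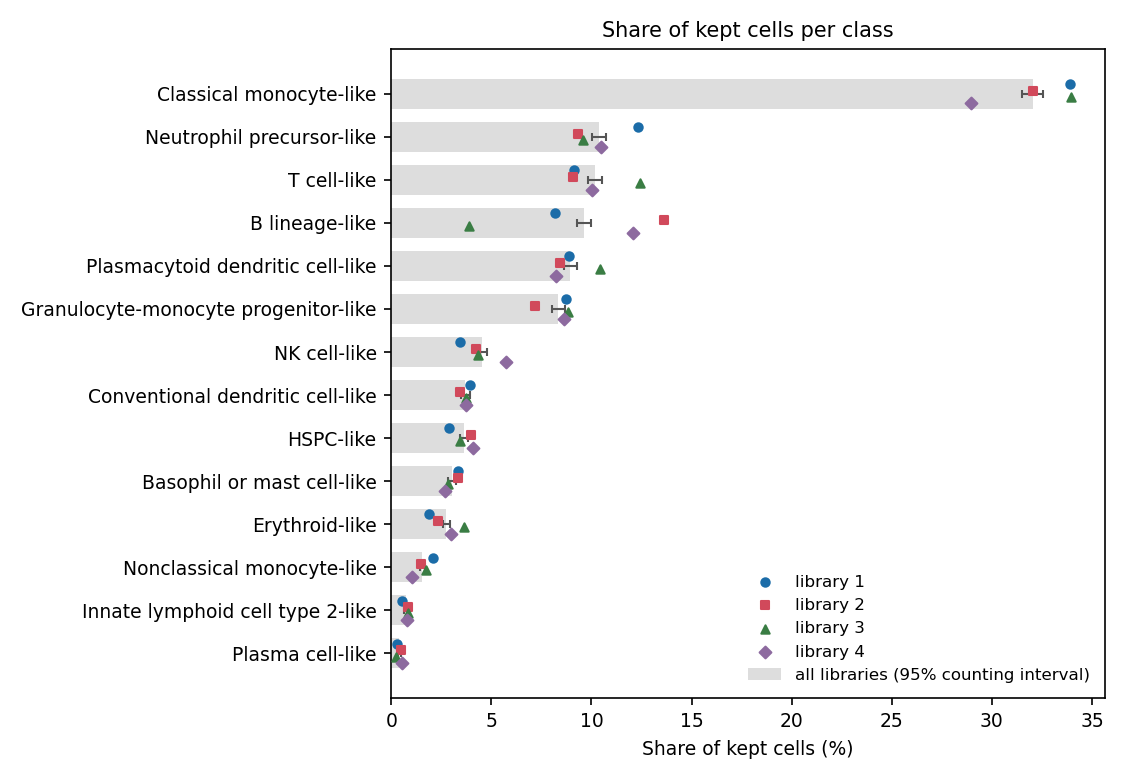
Share of kept cells per class (x axis, percent), with a bar for all 4 libraries, its 95% counting interval and a point per library. Classical monocyte-like cells lie between 29.0% and 33.9% in the libraries, and the B lineage-like points spread from 3.88% to 13.6%.

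The next comparison set classical monocyte-like against GMP-like cells, both of them mixed classes. The classical class included clusters that cycle at 99.7% and 85.9%, which passed 4 and 5 classical monocyte markers. It is therefore not a class of mature monocytes alone. GMP-like cells held clusters led by the neutrophil protease Elane beside others. The ratios average over the clusters of each class. Against the others, the Elane-led clusters were lower for 7 of 13 MHC class II genes and higher for 0. For lysosome and phagocytosis genes 9 of 24 were lower and 1 higher. For pattern recognition receptors these counts were 8 and 3 of 21, and for growth factor and cytokine receptors 10 and 3 of 22. The scavenger receptor Msr1 was 45.1-fold higher (36.9 to 55.9), the high-affinity IgG receptor Fcgr1 22.8-fold (18.8 to 28.0) and the bacterial RNA sensor Tlr13 24.8-fold (20.4 to 30.4). The monocyte and macrophage transcription factor Mafb was 36.3-fold higher (28.4 to 47.3). The stem cell factor receptor Kit was 108-fold lower (80.4 to 149), at 0.632 against 68.4 CPM, and the progenitor transcription factor Myb was 17.5-fold lower (16.5 to 18.7). Msr1 lies on chromosome 8 from 39581685 to 39642673 and Kit on chromosome 5 from 75574916 to 75656722 (mm10), both as protein-coding genes.

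Of 411 list members counted between these classes, 136 were higher in the monocytes, 44 were lower and 231 were neither. TMM factors moved every log2 ratio of this comparison up by 0.12 and gave 145 higher and 40 lower. Interferon-stimulated genes were higher for 16 of 20 members and lower for none. Part of the monocyte level comes from a classical cluster of 246 cells, in which 20 of 20 members were higher than in the other classical clusters. The largest ratios among those at 50 CPM or more were 35.1 for Ifi27l2a (32.7 to 37.6), 32.0 for Irf7 (25.5 to 40.6), a master regulator of type I interferon, and 20.7 for Ifi204 (18.3 to 23.4), a DNA sensor. Pattern recognition receptors were higher for 16 of 21, lysosome and phagocytosis genes for 15 of 24 and NF-kB inflammatory genes for 12 of 22, with none lower in any of the 3 lists. Of the MHC class II presentation genes 8 of 13 were higher, among them the invariant chain Cd74 at 22.7-fold (20.9 to 24.7) and the protease Ctss at 11.3-fold (10.9 to 11.7). Immediate-early genes were higher for 10 of 20, with Klf2 at 7.97-fold (7.42 to 8.58), and lower for 1. Matrix genes were higher for 8 of 19 and lower for 1. The collagenase Mmp8 was 21.5-fold higher (18.6 to 24.98), and Lgals3, which encodes galectin-3, was 8.79-fold higher (8.64 to 8.95).

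Among receptors, 9 of 22 chemokine and homing receptors were higher and 1 was lower, with Ccr1 at 11.7-fold (10.2 to 13.6). Growth factor and cytokine receptors were higher for 10 of 21 and lower for 1. The interleukin-10 receptor Il10ra was 9.003-fold higher (8.23 to 9.87), the interleukin-17 receptor Il17ra 3.81-fold (3.66 to 3.98) and the interleukin-6 receptor Il6ra 3.66-fold (3.52 to 3.80). In the IL-1 system and inflammasome list 8 of 18 were higher and 2 lower, with the signalling kinase Irak2 at 3.10-fold (2.89 to 3.33). Of the genes for reactive oxygen production and defence 4 of 21 were higher, including the NADPH oxidase subunit Cybb at 5.003-fold (4.90 to 5.11), and none was lower. Myeloid transcription factors went both ways, with 11 of 24 higher and 6 lower. Irf5 was 6.74-fold higher (6.31 to 7.20), and the granulocytic factor Cebpe was 10.7-fold lower (10.1 to 11.4). Part of the GMP-like class carried the Cebpe value, at 426 CPM in the 2 clusters led by Elane and 22.6 CPM in the 2 others, against 17.2 CPM in the monocytes.

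In the S phase list 16 of 28 were lower in the monocytes, 12 were neither and none was higher, with Cdca7 4.31-fold lower (4.11 to 4.52) and the chromatin remodeller Hells 3.43-fold lower (3.29 to 3.57). No member of the 28-gene G2/M list was counted in either direction (1 higher with TMM), and its median log2 ratio was 0.23. Both lists average over classical clusters that cycle at 11.4% to 99.7%, whereas the GMP-like clusters cycle at 83.8% to 99.3%. Heat shock genes were lower for 5 of 12 (3 with TMM) and higher for 1, with the mitochondrial chaperonin Hspd1 3.52-fold lower (3.44 to 3.60) and Hsp90aa1 2.88-fold lower (2.84 to 2.91). The metal-binding protein gene Mt1 was 10.1-fold lower (9.52 to 10.7), in a glucocorticoid-responsive list with 3 of 12 higher and 2 lower. Glycolysis (3 of 19 higher, 3 lower, the latter 2 with TMM), oxidative phosphorylation (0 of 24 in both directions), cholesterol synthesis (2 of 21 higher, 2 lower) and chromatin regulators (2 of 27 higher, 4 lower) held few counted members. The medians of the interferon, pattern recognition, lysosome and MHC class II lists lay above all 10000 random lists (percentile 100). So did those of the NF-kB, matrix, immediate-early, and growth factor and cytokine receptor lists. The IL-1 and the chemokine and homing receptor lists lay at 99.99, so the percentile hardly tells these lists apart. The S phase median lay below all random lists (percentile 0). The clusters were made without the list genes, and the ratios were checked over the 4 libraries by their direction in each and by leaving out each library in turn.

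**Figure D2:**
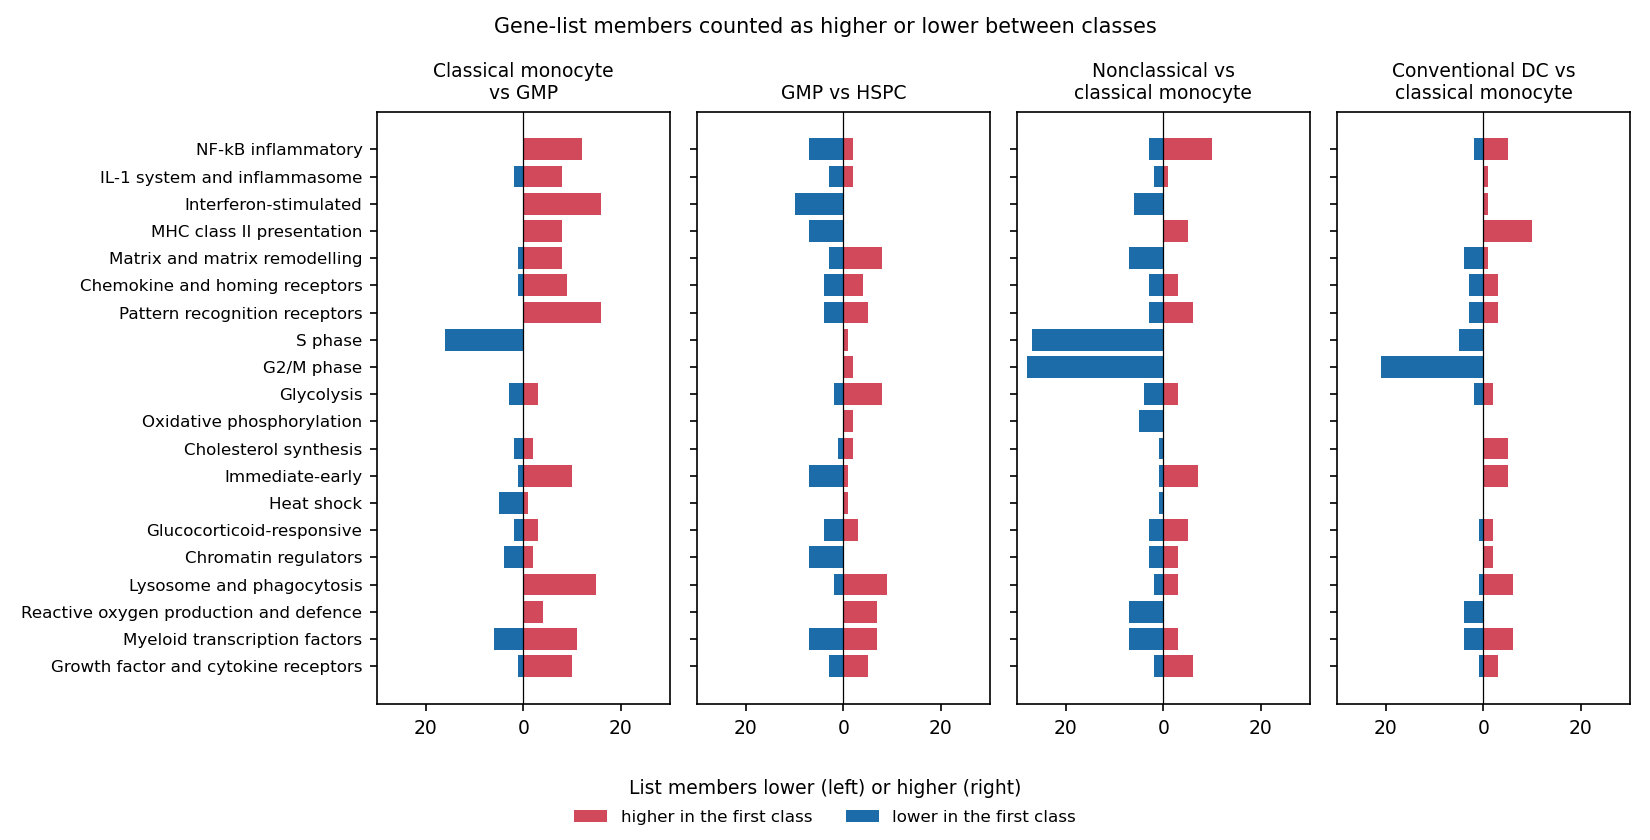
Number of members of each gene list (y axis) counted as higher (right, red) or lower (left, blue) in the first class of each of the 4 comparisons (x axis, genes). In the first panel 16 interferon-stimulated genes are higher and 16 S phase genes lower, and in the third panel 28 G2/M genes are lower.

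GMP-like cells were next set against HSPC-like cells, committed myeloid against early progenitors. The HSPC-like class was a single cluster whose first leading gene was Dntt, a member of the B lineage marker list. The comparison may therefore hold more than a step to the myeloid path. The transcription factors of myeloid differentiation Klf4, Cebpd and Cebpb were 10.8-fold (8.50 to 13.9), 6.49-fold (5.604 to 7.56) and 6.46-fold (5.601 to 7.497) higher in GMP-like cells. The Klf4 value came from part of the class: the level was 126 CPM in 2 of its clusters and 2.73 CPM in the 2 led by Elane, below the 7.09 CPM of HSPC-like cells. Mt1 was 10.3-fold higher (8.87 to 12.1) and the IgG receptor Fcgr3 9.30-fold (7.82 to 11.1). The DNA demethylase Tet1 was 10.1-fold lower (8.70 to 11.9), Runx2 6.32-fold lower (6.04 to 6.61), Tcf4 5.95-fold lower (5.65 to 6.27) and the transforming growth factor receptor Tgfbr2 6.25-fold lower (5.54 to 7.05). Kit was 3.34-fold lower (3.16 to 3.53). Klf4 lies on chromosome 4 from 55527143 to 55532466 and Mt1 on chromosome 8 from 94179082 to 94180327 (mm10).

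Of 414 members counted, 68 were higher in GMP-like cells, 69 were lower and 277 were neither. This split depends on scaling: TMM factors moved every log2 ratio up by 0.48 and gave 134 higher and 47 lower, so that 74.0% of counted members were higher in place of 49.6%. The median log2 ratio of all genes was -0.33 before that shift. With called doublets kept, the split moved the other way, to 40 higher and 80 lower. Reactive oxygen production and defence genes were higher for 7 of 21 (12 with TMM) and lower for none under both scalings. Among them the peroxiredoxin Prdx5 was 4.89-fold higher (4.65 to 5.14) and the oxidase component Ncf4 3.88-fold (3.55 to 4.25). Lysosome and phagocytosis genes were higher for 9 of 24 (15 with TMM) and lower for 2 (1 with TMM), with Tyrobp at 3.30-fold (3.17 to 3.43) and Lamp1 at 3.22-fold (3.03 to 3.43). Glycolysis genes were higher for 8 of 19 (12 with TMM) and lower for 2 under both. Enolase (Eno1) was 3.01-fold higher (2.79 to 3.25) and Pgam1 2.55-fold (2.44 to 2.67), whereas the glucose transporter Slc2a3 was 5.85-fold lower (5.19 to 6.60). Matrix genes were higher for 8 of 21 under both scalings and lower for 3 (2 with TMM), with Lgals3 at 6.02-fold (5.49 to 6.61). Its level was 462 CPM in the 2 clusters not led by Elane and 28.97 CPM in the 2 led by it, below the 47.8 CPM of HSPC-like cells. With the called doublets kept in, the Lgals3 ratio fell to 1.47 and was no longer counted.

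Interferon-stimulated genes were lower for 10 of 20 and higher for none, which TMM scaling changed to 8 lower and 2 higher. MHC class II genes were lower for 7 of 13 (4 with TMM) and higher for none. Immediate-early genes were lower for 7 of 20 (3 with TMM) and higher for 1 (2 with TMM), with Jund 3.68-fold lower (3.46 to 3.92). Chromatin regulators were lower for 7 of 27 (3 with TMM) and higher for none, among them the histone demethylase Kdm5b at 3.04-fold (2.80 to 3.30). NF-kB genes were lower for 7 of 21 (4 with TMM) and higher for 2 under both, with Tnfaip2 3.64-fold higher (3.06 to 4.36). In the IL-1 list 2 of 17 were higher (7 with TMM) and 3 lower, with Il18rap 4.79-fold lower (4.26 to 5.40). Among the matched random lists, which a common shift of all ratios leaves unchanged, the IL-1 median lay at percentile 99.99. The NF-kB median lay at 17.26, that of the immediate-early list at 4.44 and that of the interferon list at 1.31. Those of the MHC class II and chromatin lists lay at 0.63 and 0.2.

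Pattern recognition receptors split into 5 higher and 4 lower of 21 (7 and 3 with TMM), and chemokine and homing receptors into 4 and 4 of 24 (7 and 3 with TMM). Myeloid transcription factors split into 7 and 7 of 25 (9 and 6 with TMM), glucocorticoid-responsive genes into 3 and 4 of 12 (4 and 3 with TMM), and growth factor and cytokine receptors into 5 and 3 of 21 (9 and 2 with TMM). The GM-CSF receptor Csf2ra was 4.17-fold higher (3.74 to 4.66), and the interferon-gamma receptor Ifngr1 was 3.12-fold higher (2.92 to 3.34). In the S phase list 1 of 28 was higher (5 with TMM), the ribonucleotide reductase subunit Rrm2 at 3.17-fold (2.87 to 3.51). In the G2/M list 2 of 28 were higher, a count that rose to 17 with TMM scaling. Oxidative phosphorylation had 2 of 24 higher (11 with TMM), cholesterol synthesis 2 of 21 higher (4 with TMM) and 1 lower, and heat shock 1 of 12 higher (2 with TMM). Among matched random lists the G2/M median lay at percentile 99.99, oxidative phosphorylation at 99.51 and S phase at 95.93. Cholesterol synthesis lay at 85.3 and heat shock at 77.36.

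Nonclassical were then set against classical monocyte-like cells, both from marrow. The names are those of the patrolling and the inflammatory form of blood monocyte, but the classical class here includes clusters that cycle at 99.7% and 85.9%. Cd83, an activation marker, was 103-fold higher in the nonclassical cells (74.7 to 143), the anti-apoptotic gene Bcl2a1b 97.6-fold (79.0 to 121), the IgG receptor Fcgr4 57.8-fold (49.7 to 67.3) and the cytokine gene Il1b 21.8-fold (17.8 to 26.5). The Il1b ratio ranged from 7.26 to 34.6 in the libraries. The homing receptor Sell (L-selectin) was 14.8-fold lower (10.7 to 21.2) and Mmp8 24.1-fold lower (11.1 to 65.7). Cd83 lies on chromosome 13 from 43784775 to 43803132, Fcgr4 on chromosome 1 from 171018920 to 171029761 and Il1b on chromosome 2 from 129364570 to 129371139 (mm10).

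Of 407 members counted, 53 were higher, 114 lower and 240 neither. Proliferation genes gave many of the lower calls, with 27 of 28 S phase genes and 28 of 28 G2/M genes lower. The classical class holds 2 clusters that cycle at 99.7% and 85.9%, and 2 of its others, at 12.4% and 11.4%, lie below the 14.4% of the nonclassical cells, so these calls are not read as a difference from each classical cluster. The kinase gene Aurkb was at 0.642 against 60.5 CPM, a ratio of 0.0106 (0.000268 to 0.0591). Ratios for Rrm2 and Tyms, both of nucleotide synthesis, were 0.0158 (0.00191 to 0.0571) and 0.0719 (0.0329 to 0.137). NF-kB genes were higher for 10 of 22 and lower for 3, with the NF-kB regulator Nfkbiz at 9.06-fold (8.29 to 9.88). Immediate-early genes were higher for 7 of 19 and lower for 1 (2 with TMM), with Jund at 4.15-fold (3.68 to 4.66) and Klf2 at 3.90-fold (3.63 to 4.18). Of the MHC class II genes 5 of 13 were higher and none lower (1 with TMM), with Cd74 at 6.78-fold (6.53 to 7.04). Pattern recognition receptors were higher for 6 of 21 (4 with TMM) and lower for 3, with the RNA sensor Tlr7 at 4.76-fold (4.04 to 5.58) and the peptidoglycan sensor Nod1 at 3.52-fold (2.93 to 4.19).

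Glucocorticoid-responsive genes were higher for 5 of 12 and lower for 3. Zbtb16 was 23.3-fold higher (20.6 to 26.5) and the kinase Sgk1 5.48-fold (4.63 to 6.44), and Cebpd was 2.79-fold lower (2.27 to 3.45). Growth factor and cytokine receptors were higher for 6 of 21 and lower for 2, with Tgfbr2 at 5.93-fold (5.23 to 6.70). Chromatin regulators divided evenly, with 3 of 27 higher and 3 lower. Kdm5b was 5.28-fold higher (4.28 to 6.45) and the DNA methyltransferase Dnmt3a 5.24-fold (4.29 to 6.35). The histone methyltransferase Ezh2 was 5.15-fold lower (3.86 to 7.03) and the maintenance methyltransferase Dnmt1 4.64-fold lower (3.51 to 6.28). The classical reference includes clusters that cycle at 99.7% and 85.9%, and whether these carry the Ezh2 and Dnmt1 values was not tested. Chemokine and homing receptors gave 3 of 20 higher, led by the integrin Itga4 at 3.07-fold (2.91 to 3.22), and 3 lower. Myeloid transcription factors gave 3 of 23 higher, led by Runx2 at 8.15-fold (7.30 to 9.08), and 7 lower.

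Matrix genes were lower for 7 of 19 and higher for none, and reactive oxygen genes lower for 7 of 21 and higher for none, with thioredoxin (Txn1) 2.81-fold lower (2.48 to 3.20). Oxidative phosphorylation genes were lower for 5 of 24 (11 with TMM) and higher for none, led by Cox5b at 2.57-fold (2.27 to 2.92). Interferon-stimulated genes were lower for 6 of 20 and higher for none, with a list median log2 ratio of -0.55. Part of the reference level comes from a classical cluster of 246 cells, in which 20 of 20 members were higher than in the other classical clusters. Total counts without that cluster are given in the closing sections. They do not show this list alone, so how many of its lower calls rest on that cluster is not reported here. Glycolysis (3 of 19 higher, 4 lower, or 2 and 5 with TMM), lysosome and phagocytosis (3 of 23 higher, 2 lower, or 2 and 3 with TMM), the IL-1 list (1 of 18 higher, 2 lower, or 1 and 3 with TMM), cholesterol synthesis (1 of 21 lower) and heat shock (1 of 12 lower, 3 with TMM) held fewer. The nonclassical class rests on 451 cells and 1558647 UMIs, which sets the width of its intervals, and TMM scaling, which moved every log2 ratio down by 0.16, gave 48 higher and 130 lower.

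**Figure D3:**
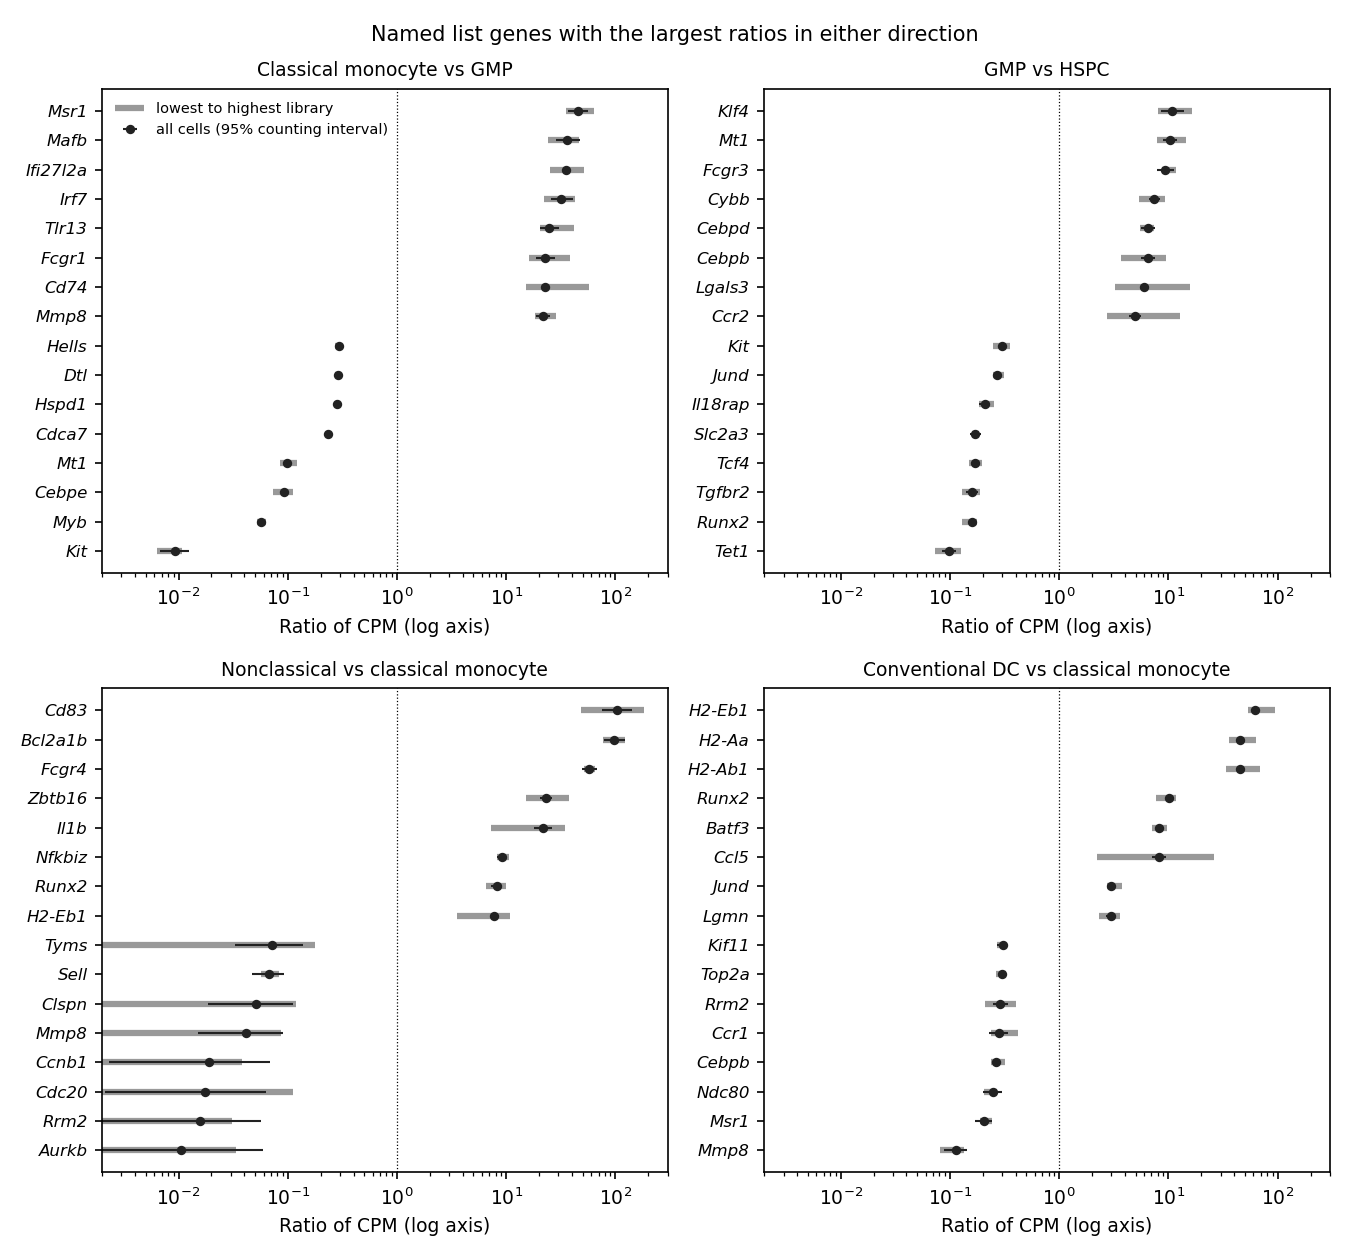
Ratio of CPM between the 2 classes (x axis, log scale) for the 8 named genes with the highest and the 8 with the lowest ratio in each comparison (y axis); points are ratios over all cells with 95% counting intervals, and grey bars run from the lowest to the highest library. Bars that reach the left edge hold a library with no count in the nonclassical class; Cd83 lies at 103 and Kit, in the first panel, at 0.00924.

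The last comparison set conventional dendritic cell-like against classical monocyte-like cells. The dendritic class is 1 cluster, which passed 7 dendritic and also 5 classical monocyte markers. Antigen presentation genes were higher in the dendritic cells for 10 of 13 members and lower for none. The class II chains H2-Eb1, H2-Aa and H2-Ab1 were 62.7-fold (60.3 to 65.2), 45.3-fold (43.9 to 46.6) and 44.9-fold (43.7 to 46.3) higher. The transcription factors Runx2 and Batf3, the latter required for cross-presenting dendritic cells, were 10.1-fold (9.50 to 10.7) and 8.28-fold (7.58 to 9.05) higher. The monocyte factor Cebpb was 3.77-fold lower (3.47 to 4.11), Msr1 4.91-fold lower (4.15 to 5.87) and Mmp8 8.83-fold lower (7.01 to 11.3). H2-Eb1 lies on chromosome 17 from 34305867 to 34316674 (mm10).

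Of 409 members counted, 55 were higher in the dendritic cells, 51 lower and 303 neither. G2/M genes were lower for 21 of 28 and higher for none, with the spindle gene Ndc80 4.06-fold lower (3.35 to 4.96) and topoisomerase Top2a 3.33-fold lower (3.15 to 3.53). S phase genes were lower for 5 of 28, with Rrm2 3.46-fold lower (2.96 to 4.07). The 2 classical clusters that cycle at 99.7% and 85.9% are part of the reference, and 2 others, at 12.4% and 11.4%, lie below the 25.05% of the dendritic cells, so these calls are not read for every classical cluster. Cholesterol synthesis genes were higher for 5 of 21 and lower for none, including the demethylase Cyp51 at 2.65-fold (2.38 to 2.95). Immediate-early genes were higher for 5 of 20 and lower for none (1 with TMM), with Jund at 3.01-fold (2.80 to 3.23). NF-kB genes were higher for 5 of 22 (3 with TMM) and lower for 2. Reactive oxygen genes were lower for 4 of 21 and higher for none, with Prdx5 3.16-fold lower (3.05 to 3.29). Matrix genes were lower for 4 of 19 and higher for 1.

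Myeloid transcription factors gave 6 of 24 higher and 4 lower, and lysosome and phagocytosis genes 6 of 24 higher and 1 lower (2 with TMM). Chemokine and homing receptors gave 3 of 21 higher and 3 lower, with Ccr1 3.59-fold lower (2.95 to 4.40), pattern recognition receptors 3 of 21 in both directions (2 higher with TMM), and growth factor and cytokine receptors 3 of 20 higher (1 with TMM) and 1 lower. The other lists gave at most 2 calls a direction: glycolysis 2 higher and 2 lower of 19 (2 and 3 with TMM), glucocorticoid-responsive genes 2 and 1 of 12 (1 and 2 with TMM), chromatin regulators 2 and 0 of 27, interferon-stimulated genes 1 and 0 of 20 (Bst2 at 2.19-fold, 2.08 to 2.30), the IL-1 list 1 and 0 of 18, and none of 24 oxidative phosphorylation and 12 heat shock genes. At Leiden resolution 0.5, where the dendritic cell-like class grew to 5.23% of cells, 83 members were higher in place of 55. TMM scaling moved every log2 ratio down by 0.12 and gave 48 higher and 55 lower.

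Cycling was compared between classes from the G2/M list after thinning each cell to 2000 UMIs. In neutrophil precursor-like cells 91.3% (90.2 to 92.3) had at least 3 such UMIs and in GMP-like cells 90.5% (89.3 to 91.7), with 87.7% to 93.1% in the libraries for the latter. The share was 65.1% in erythroid-like cells (61.4 to 68.6), 53.1% in basophil or mast cell-like cells (49.4 to 56.7), 49.8% in classical monocyte-like cells (48.8 to 50.9) and 42.3% in HSPC-like cells (39.2 to 45.5). Shares were 25.05% in conventional dendritic cell-like (22.4 to 27.8), 23.3% in plasmacytoid dendritic cell-like (21.6 to 25.003) and 22.7% in B lineage-like cells (21.0 to 24.5). They were 16.9% in NK cell-like, 15.7% in T cell-like, 14.5% in type 2 innate lymphoid-like, 14.4% in nonclassical monocyte-like and 5.56% in plasma cell-like cells, with median depths of 3425, 4110, 2494.5, 3132 and 12418 UMIs. These shares do not mark a level without cycling, since single clusters lay lower, down to 1.27% in a plasmacytoid dendritic cell-like cluster.

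The class shares averaged over clusters that differed. In classical monocyte-like cells, 2 clusters at 99.7% and 85.9% lay beside 3 at 32.7%, 12.4% and 11.4%. In plasmacytoid dendritic cell-like cells, a cluster at 100% held 66.0% of the cycling cells, and the others lay at 25.5%, 2.32% and 1.27%. In B lineage-like cells the 3 clusters lay at 100%, 23.7% and 7.18%.

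Without thinning, the shares were 98.5% in neutrophil precursor-like, 99.4% in GMP-like, 75.5% in classical monocyte-like, 74.5% in HSPC-like and 33.7% in nonclassical monocyte-like cells. Thinning left out 293 of 9281 classical monocyte-like, 44 of 2416 GMP-like, 62 of 1050 HSPC-like and 48 of 451 nonclassical monocyte-like cells. Larger parts were left out of other classes. These were 30.3% of type 2 innate lymphoid-like, 19.2% of B lineage-like and 14.4% of basophil or mast cell-like cells. For erythroid-like and NK cell-like cells they were 12.8% and 11.5%. Cycling shares cover only the deeper cells of each class. Summed S phase CPM was 3647 in GMP-like and 3141 in HSPC-like cells against 1736 in classical monocyte-like and 406 in nonclassical monocyte-like cells. Summed G2/M CPM was 8848 in neutrophil precursor-like, 6224 in classical monocyte-like, 5116 in GMP-like, 3483 in HSPC-like and 660 in nonclassical monocyte-like cells. By CPM the classical monocyte-like cells thus lay above the GMP-like cells, the reverse of the order of the cell shares, so no order between these classes is read.

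**Figure D4:**
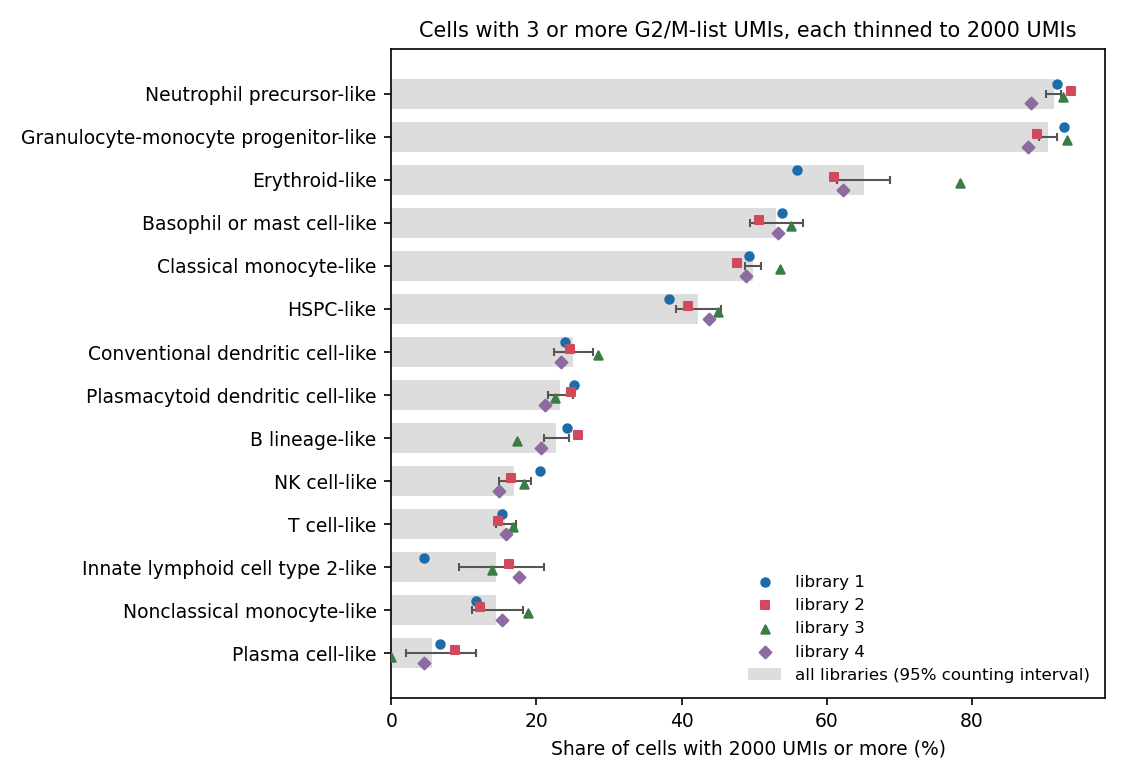
Share of cells with at least 3 UMIs from the G2/M list after thinning to 2000 UMIs (x axis, percent) per class, with a bar for all libraries, its 95% counting interval and a point per library. Neutrophil precursor-like (91.3%) and GMP-like cells (90.5%) lie highest, and nonclassical monocyte-like cells (14.4%) low.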

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

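No test in this part was chosen after the result was seen. Each of 35 sets of library values was checked for a library far from the other 3, by the gap to its nearest neighbour as a part of the whole range. Chance alone marks about 1 set in 20, and 2 sets were marked.

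The share of GMP-like cells was 7.19% in library 2, against 8.71%, 8.85% and 8.63% in the others, and the gap took 0.864 of the range, beyond the 95% critical value of Dixon's test. The share of cells like innate lymphoid cells of type 2 was 0.558% in library 1, against 0.815%, 0.819% and 0.793% in the others, with a gap of 0.900 of the range. Neither difference was tied to a condition, since the libraries are not tied to labelled samples, and no explanation was tested.

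Haemoglobin transcripts took 18.1% of the 672775 UMIs in the 821 barcodes with fewer than 500 genes, which no comparison used, against 0.0895% in the kept cells. The value was 12.9%, 10.05%, 12.5% and 30.04% in libraries 1 to 4. What these barcodes held was not tested, and the sort was directed against the erythroid protein Ter119.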

How the results depend on the processing

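Every alternative was planned except leaving out the interferon-led cluster of classical monocyte-like cells, which was chosen after seeing the data. No paired analysis was possible because the replicate numbers of the stroke and control samples are not tied to the 4 libraries. Between classes, pairing within libraries is possible, and the median of the library ratios gave 133 higher and 45 lower, 70 and 67, 53 and 119, and 57 and 51 in the 4 comparisons in the order of the report. The comparison of mature neutrophils and the comparisons of stroke with control were not run under any setting.

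Of 210 main shares, cycling shares and counts under the alternatives, 168 stayed within their interval (shares) or within 1.5 times their main count, and 42 moved beyond it. The cause was not tested for any of them, except that TMM factors shift all ratios of a comparison by construction.

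At Leiden resolution 0.5, 83 list members were higher in conventional dendritic cell-like than in classical monocyte-like cells (55 in the report). Shares were 33.8% for classical monocyte-like, 11.1% for neutrophil precursor-like, 5.19% for GMP-like and 5.23% for conventional dendritic cell-like cells, and cycling was 54.6% in classical monocyte-like and 84.9% in GMP-like cells. At resolution 2, shares were 8.81% for GMP-like, 2.79% for conventional dendritic cell-like and 2.46% for HSPC-like cells, with cycling at 47.2% in classical monocyte-like and 38.9% in HSPC-like cells. With 4000 variable genes, shares were 32.8% for classical monocyte-like, 9.68% for neutrophil precursor-like and 4.22% for conventional dendritic cell-like cells, and classical monocyte-like cycling was 51.1%. With list genes among the variable genes, the same 3 shares were 31.1%, 9.86% and 5.44%, and that cycling share was 53.2%. A minimum of 1000 genes gave shares of 33.8% for classical monocyte-like, 7.63% for GMP-like, 4.43% for conventional dendritic cell-like and 3.99% for HSPC-like cells, with cycling at 51.2% in classical monocyte-like and 88.96% in GMP-like cells.

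With called doublets kept, 40 members were higher in GMP-like than in HSPC-like cells (68 in the report). Shares were then 11.4% for neutrophil precursor-like, 7.22% for GMP-like, 3.12% for conventional dendritic cell-like and 1.26% for nonclassical monocyte-like cells, and GMP-like cycling was 89.2%. The Fn1 ratio of GMP-like to HSPC-like cells reversed there, from 2.64 to 0.611, and the cause was not tested. TMM scaling raised the count in that comparison to 134 higher and lowered the other to 47.

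Leaving out each library in turn gave 132 to 138 higher and 42 to 47 lower for classical monocyte-like against GMP-like cells, and 64 to 68 and 67 to 75 for GMP-like against HSPC-like cells. It gave 52 to 59 and 107 to 115 for nonclassical against classical, and 55 to 58 and 49 to 52 for dendritic against monocyte-like cells. Shares lay between 31.4% and 33.3% for classical monocyte-like, 9.83% and 10.7% for neutrophil precursor-like, 8.18% and 8.72% for GMP-like, 3.63% and 3.79% for conventional dendritic cell-like, 3.45% and 3.83% for HSPC-like and 1.40% and 1.76% for nonclassical monocyte-like cells. Cycling lay between 48.6% and 50.6% in classical monocyte-like, 89.6% and 91.7% in GMP-like, 41.5% and 43.2% in HSPC-like and 12.8% and 15.5% in nonclassical monocyte-like cells.

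Of 199 named gene ratios, 150 kept their call under every alternative run. The most calls lost to a single setting were 17, at each of resolution 0.5, resolution 2 and doublets kept. Without the interferon-led cluster the counts were 134 and 44, 53 and 111, and 62 and 51 for the 3 comparisons with classical monocyte-like cells, and 1 named gene ratio lost its call. Depth limits the nonclassical class most: on simulated counts at its depth, 89.0% of genes changed 2.5-fold were called.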

Other observations

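The cluster and class pairs in this part were chosen after the clusters were seen, as were the tests of RNA from other cells, of CD3 and Cd19 transcription, of a common sort difference, of doublets as the make-up of the whole interferon-led cluster and of a single library. The other tests were fixed before their results were seen.

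Within the progenitors, the clusters led by the neutrophil protease Elane were set against the other GMP-like clusters. Cebpe and Gfi1, transcription factors of the granulocyte path, were 18.8-fold (17.3 to 20.5) and 10.02-fold higher, and the G-CSF receptor Csf3r was 2.70-fold higher. Klf4 and Irf8, factors of the monocyte path, were 46.2-fold and 28.8-fold lower, as were the chemokine receptor Ccr2 at 15.9-fold and the M-CSF receptor Csf1r at 14.0-fold. Of 414 list members 36 were higher and 73 lower. No S phase gene of 28 was counted, and 1 of 28 G2/M genes was lower.

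Among neutrophil precursor-like cells, the cluster with the smaller cycling share (78.6% against 99.8%) carried more transcripts of granule metalloproteinases. Mmp8 was 29.5-fold (21.2 to 42.1) and Mmp9 13.9-fold (11.4 to 17.1) higher, and 8 of 18 matrix genes were higher and none lower. Mmp8 and Mmp9 are also on the marker list of mature neutrophils. Of the G2/M genes 17 of 28 were lower, with Aurkb 5.64-fold and Top2a 4.33-fold lower.

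Plasmacytoid were set against conventional dendritic cell-like cells. The endosomal RNA sensor Tlr7 was 4.55-fold higher, the protease Ctsl 26.7-fold and Irf8 4.42-fold, and 10 of 20 cholesterol synthesis genes were higher and none lower. Pattern recognition receptors were lower for 14 of 21 and higher for 1. MHC class II genes were lower for 10 of 13, with H2-Eb1 9.86-fold lower, and Mafb was 86.1-fold lower. Cd4, whose protein the sort targeted, was at 52.3 CPM in plasmacytoid dendritic cell-like, 11.5 CPM in T cell-like and 0.0575 CPM in classical monocyte-like cells.

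A cluster of 246 cells, 2.65% of the classical monocyte-like class, was led by interferon-stimulated genes. Against the other classical monocyte-like clusters 20 of 20 such genes were higher, with Ifit3 at 143-fold (127 to 163), Rsad2 at 79.1-fold and Irf7 at 18.9-fold. The chemokine Cxcl10, a member of the NF-kB inflammatory list, was 124-fold higher (110 to 140). Genes of both lists were kept out of the variable genes used for clustering, but genes outside the lists, such as its leading gene Ifi205, were not. The cluster was picked because several members of the interferon-stimulated list were among its 10 leading genes. The count on the same list therefore describes the cluster and is no separate support for it. MHC class II genes were higher for 7 of 13, with H2-Aa at 15.9-fold, and 26 of 28 S phase and 28 of 28 G2/M genes were lower. The clusters set against it include 2 that cycle at 99.7% and 85.9%. Its own cycling share of 11.4% was close to the 12.4% of the largest other cluster, so the lower proliferation genes do not set it apart.

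A single library as the source is argued against, since the highest share of the cluster in 1 library was 33.3%. The cluster made up 2.01%, 3.54%, 2.96% and 2.07% of the class in libraries 1 to 4. Doublets were tested in 2 ways. By the test fixed before, in which a median log2 ratio of at least 1 for another class's markers would speak for doublets, 5 classes met the bound. The highest value was 3.37, for basophil or mast cells, followed by 2.42 for plasmacytoid dendritic cells, 2.04 for T cells, 1.98 for the B lineage and 1.52 for conventional dendritic cells. Doublets may thus be present. Of the basophil or mast cell marker UMIs 145 of 163 lay in 3 cells, as did 86 of 102 for the B lineage and 28 of 36 for T cells. Those of plasmacytoid and conventional dendritic cells were spread wider, over 234 and 71 of the 246 cells. One plasmacytoid marker, Bst2, is itself an interferon-stimulated gene and gave 867 of the 1283 UMIs. Without it the value was 2.39, with 416 UMIs over 147 cells, a count made after the result was seen. For the whole cluster, the highest median level of another class's markers was 7.98%, that of conventional dendritic cells, which argues against doublets as its make-up. A response to handling stays open: the median log2 ratio of the immediate-early list was 0.68, between the bound of 1 that would speak for it and that of 0.5 that would speak against it. No biological explanation was tested, since the groups of the design are not tied to libraries.

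T cell-like and B lineage-like cells were present in a fraction depleted with antibodies against CD3, CD4, CD8a and CD19. Because the tested genes helped to name these classes, clusters were made and named again without Cd3d, Cd3e, Cd3g, Cd79a, Cd79b and Cd19. All B lineage-like cells of the report kept their name, but 48.1% of T cell-like cells did. RNA released by other cells is argued against for the cells so named. Summed Cd79a and Cd79b were at 4361 CPM in B lineage-like and 16.2 CPM in classical monocyte-like cells, a ratio of 269 (254 to 286), and the CD3 genes gave a ratio of 1056 (889 to 1264). Doublets with monocytes are argued against by a median level of classical monocyte markers of 2.02% in the T cell-like and 1.33% in the B lineage-like cells of the report. A lack of transcription of the targeted genes throughout a class is argued against for the cells named without them. After thinning to 1000 UMIs, 84.9% of 1401 T cell-like cells (83.0 to 86.8) held a CD3 UMI against 14 of 9355 classical monocyte-like cells, 568 times the share. For Cd19 the shares were 12.3% of 2758 B lineage-like cells and 0.0214%, or 2 cells, a ratio of 577. A bound set by so few monocyte-like cells is easily passed, so this cannot tell what share of B lineage-like cells transcribe Cd19. Of the 1527 T cell-like cells that lost their name, 1340 fell into a cluster then named NK cell-like. There 82.2% of cells held a CD3 UMI, 549 times the share in classical monocyte-like cells, against 6.85% in the other NK cell-like cells. That cluster was picked through cells named by CD3, so for these cells the test decides nothing and the T cell name stays open. Median depths before thinning were 4110, 2531 and 6258 UMIs for the T cell-like, B lineage-like and classical monocyte-like cells of the report. Incomplete removal by the sort and low surface protein stay open, because protein was not measured. No biological explanation was tested.

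The B lineage-like share differed between libraries, with 13.6% in library 2 and 3.88% in library 3, a ratio of 3.51. Filters and doublet calls are argued against as the source, since B marker UMIs over all barcodes without any filter differed 3.31-fold (3.26 to 3.37) between those libraries. A common difference in how far the sort removed all its lineages is argued against too, since the T cell-like share moved the other way, with a ratio of 0.732 (0.661 to 0.811). A difference in the removal of B cells alone, or in the marrow itself, stays open. No biological explanation was tested, because the conditions of the libraries are not known.

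Libraries were compared in pairs within a class, over genes with at least 50 CPM. In classical monocyte-like cells the median absolute log2 ratio was 0.08 between libraries 1 and 3 and 0.13 to 0.17 between the other pairs. Libraries 1 and 3 were also the closest pair in GMP-like, neutrophil precursor-like and plasmacytoid dendritic cell-like cells. No condition was read from this.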
